A study of Mus musculus with 12 samples.

How the data were processed

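RNA of glial cells from the spinal cord (brachial and thoracic levels) of C57BL/6 mice at postnatal day 7 was measured in 12 libraries of total RNA, sequenced on a BGISEQ-500. The cells had been dissociated with papain and sorted by flow cytometry into fractions labelled eGFP, tdTomato and eGFP/tdTomato, from mice carrying an Aldh1L1-GFP and an Olig2-tdTomato reporter. Each fraction had 4 libraries, numbered 1, 2, 3 and 5. All 12 were used, and none was left unassigned.

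The authors aligned the reads with STAR to GRCm38 and deposited raw HTSeq counts per Ensembl gene, 1 file per library, without naming versions, strand mode or annotation release. Each file was checked to hold whole numbers for 53465 genes and 5 lines that name no gene, and no libraries were identical. Symbols and positions came from GENCODE M21, which held 53360 of the gene identifiers (99.8%). The 105 others stayed in the tests and were not named. Mitochondrial genes were listed at 0 counts in every library, so the mitochondrial share could not serve as a measure of quality.

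Reads counted in genes were 12.6 to 36.5 (units of 1e6) per library, which was 28.5 to 64.0% of the reads in the files. Reads outside annotated genes made up 21.2 to 57.1%, ambiguous reads 1.8 to 4.6% and reads aligned at several places 10.1 to 15.2%. The 10 most abundant genes held 10.9 to 15.6% of the gene counts, and 28244 to 46149 genes had at least 1 count. Intervals computed from counts cover counting error only, and the precision of a mean is given by the SD of its libraries. Levels are CPM scaled by TMM factors, given as the mean ± SD of 4 libraries.

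Counts were tested with edgeR 4.0.16 (quasi-likelihood F-test, robust, TMM factors, filterByExpr by group) in R 4.3.3, with all 12 libraries in 1 fit and the fraction as the only factor. Of the genes, 29361 passed the filter. P-values were adjusted by the Benjamini-Hochberg method over these genes, and genes with an adjusted p under 0.05 were called. The SE of a log2 fold change is its size over the root of F. A gene was higher or lower than both when called with a log2 fold change of at least 1 in both comparisons. No samples were taken as matched in this fit, since the labels number the libraries by set without saying what a set shares.

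Gene lists were fixed in advance: the reporter genes (2 genes, given 1 by 1) and 31 tested lists. These were pan-astrocyte, oligodendrocyte progenitor, differentiating oligodendrocyte, myelinating oligodendrocyte, neuron, motor neuron, microglia and macrophage, endothelium, mural and fibroblast, ependyma, erythrocyte, Schwann cell, cell cycle, ventral domain factors, dorsal domain factors, white matter astrocyte, grey matter astrocyte, transmitter uptake and ion transport, synapse-regulating secreted factors, synaptic adhesion and receptor genes, extracellular matrix proteoglycans, Notch, Hedgehog, BMP and TGF-beta, Wnt, reactive astrocyte, immediate early and dissociation stress, cholesterol synthesis, glycolysis, fatty acid oxidation, and complement and phagocytosis. They were tested with camera in limma 3.58.1 (correlation between genes preset at 0.01, and estimated beside it), adjusted over the lists of a comparison. Members called are given over all genes and adjusted over the list alone. The interpolation share of a gene is the level in the eGFP/tdTomato fraction between the eGFP (0%) and tdTomato (100%) levels. List medians of this share took members called between those fractions with a log2 fold change of at least 2 and a mean of at least 5 CPM in the higher one.

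Genes named in the text followed a rule set before the data were examined, as were the tests, the lists and most alternatives. It took Aldh1l1 and Olig2, and the 10 genes per direction with the largest log2 fold change against each single-reporter fraction (5 per direction between these), called, with at least 10 CPM in the higher fraction and no overlap of the libraries. Under the same conditions in both comparisons it took 15 genes above and 8 below both with the largest smaller of the 2 changes, and up to 4 members per list with at least 5 CPM, of which at most 1 did not pass. Unnamed gene models and pseudogenes were counted and not named, and some genes the rule picked are not reported here. Overlapping neighbours were checked for 147 named genes: 33 overlapped a tested gene, 3 of them over at least 20% of their length, among them Gbx2 and Rarres2. Hspa1a and Hspa1b have near-identical sequences, so reads may be shared between them.

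The fit was tested on simulated counts for all libraries, with gene means and spread estimated over all fractions. Genes changed in the eGFP/tdTomato libraries were drawn from those with a mean of at least 1 CPM. Against the eGFP libraries, the fit called 13 of 67 genes changed 2-fold (19.4%), 46 of 67 changed 4-fold (68.7%) and 54 of 66 changed 8-fold (81.8%), and 7 unchanged genes (5.8% of calls). Many 2-fold differences are therefore below reach between the eGFP/tdTomato and eGFP fractions. Alternatives were DESeq2's size factors and upper quartile scaling in edgeR, the DESeq2 1.42.0 Wald test, limma-voom, no filter or a stricter one, glmTreat against a log2 fold change of 1, only the 8 libraries compared, the replicate number as a block, and leaving out each library or each replicate number. A covariate for reads outside genes, the block with that covariate, TMM factors from genes of at least 10 mean CPM, and protein-coding genes with a mean of at least 1 CPM were chosen after seeing the data. Tables and figures were made with Python 3.11.15, pandas 2.3.3, SciPy 1.17.1 and matplotlib 3.10.9.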

Results

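Glial RNA was sequenced from the spinal cords of mice at postnatal day 7 that carried a GFP reporter named for Aldh1l1, an enzyme gene of astrocytes, and a tdTomato reporter named for Olig2, a transcription factor of the oligodendrocyte lineage and the ventral spinal cord. Cells of the brachial and thoracic levels were sorted by flow cytometry into fractions labelled eGFP, tdTomato and eGFP/tdTomato, with 4 libraries each, numbered 1, 2, 3 and 5. Reads counted in genes, in units of 1e6 per library, were 12.6 to 27.9 in the eGFP fraction, 25.5 to 36.5 in the tdTomato fraction and 23.9 to 30.3 in the eGFP/tdTomato fraction. The labels give neither the sort gates nor the number of animals per library, so the p-values measure the spread between these libraries. One library stood apart: eGFP replicate 1 had the fewest gene counts, 57.1% of its reads outside annotated genes (21.2 to 42.5% in the other libraries) and a summed 3970 CPM (counts scaled by library size) on olfactory and vomeronasal receptor genes (33.9 to 1640 in the others).

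The genes the reporters are named for followed the sort. Aldh1l1 (ENSMUSG00000030088, chromosome 6, 90486427 to 90600203, GRCm38) was at 406 ± 207 CPM (SD, n = 4) in the eGFP fraction, 722 ± 170 in the eGFP/tdTomato fraction and 3.69 ± 1.83 in the tdTomato fraction. Olig2 (ENSMUSG00000039830, chromosome 16, 91225457 to 91228677) was at 5.76 ± 3.06, 74.4 ± 30 and 258 ± 80.1 CPM in the same order, and its ranges over the 4 libraries of each fraction (1.73 to 8.75, 41.5 to 106 and 175 to 361) did not overlap. In the edgeR fit, Olig2 was 12.8-fold higher in the eGFP/tdTomato than in the eGFP fraction (log2 fold change 3.68 ± 0.43, SE, adjusted p = 0.000189) and 3.46-fold lower than in the tdTomato fraction (−1.79 ± 0.40, adjusted p = 0.00251, or 0.0549 when tested against a log2 fold change of 1). Aldh1l1 did not pass between the eGFP/tdTomato and eGFP fractions (0.83 ± 0.35, adjusted p = 0.404). Since the cells were sorted on these reporters, neither gene's difference is a finding.

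**Figure D1:**
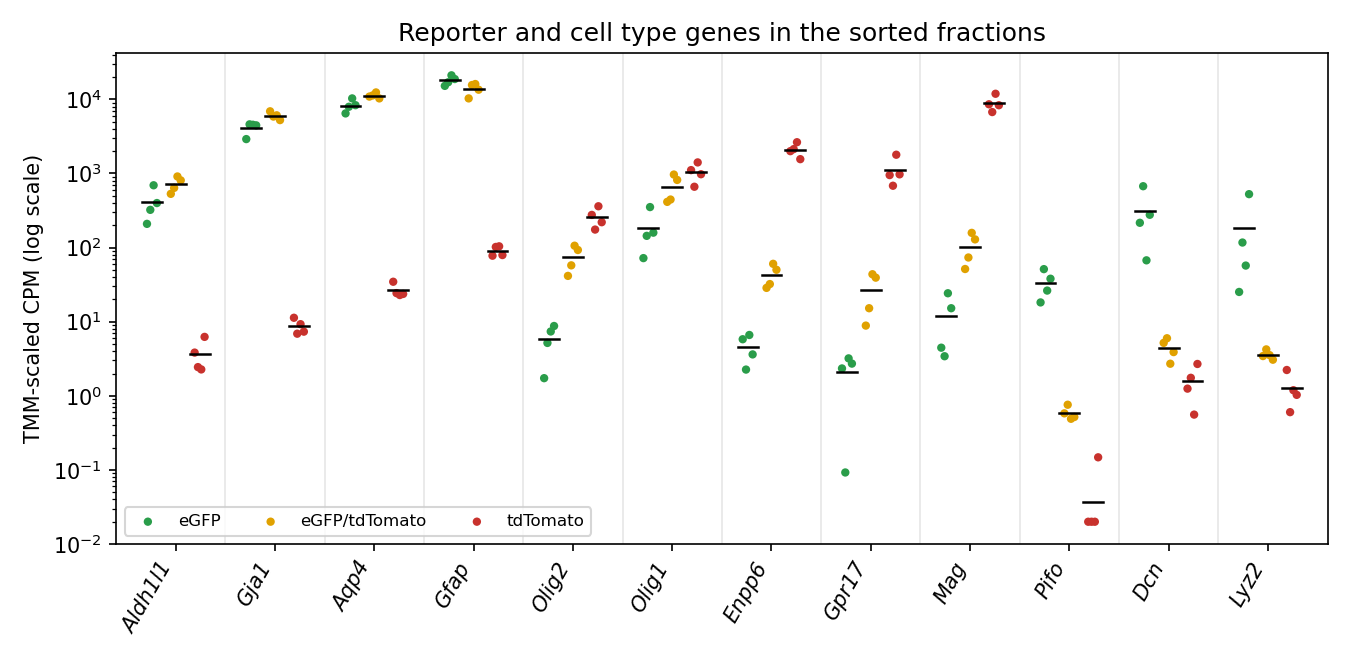
Level of 12 genes in each library, in TMM-scaled CPM on a log axis, with a point per library (4 per fraction) and a bar at the mean of the fraction. Olig2 lay between 41.5 and 106 CPM in the eGFP/tdTomato libraries, above every eGFP and below every tdTomato library, and libraries with 0 counts are drawn at the bottom of the axis.

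How cells with both reporters differ from cells of the eGFP fraction is the question of the first comparison. With both reporters, 12 of 28 myelinating, 6 of 20 differentiating, 4 of 20 progenitor and 7 of 29 cell cycle genes were higher, and 13 of 14 ependyma, 11 of 19 microglia and macrophage and 5 of 14 mural and fibroblast genes were lower. As lists, ependyma alone was called with an estimated correlation (adjusted p = 0.027), where the others were at 0.0983, 0.0911, 0.112, 0.0983, 0.0942 and 0.0654 in the order given. Enpp6, a phosphodiesterase of newly differentiating oligodendrocytes, was 9.36-fold higher (42.8 ± 15 against 4.58 ± 2.00 CPM, SD, n = 4 each), and Chst7, a chondroitin sulfotransferase (ENSMUSG00000037347, chromosome X), rose by 3.32 ± 0.39 on the log2 scale (11.2 ± 2.80 against 1.10 ± 0.464 CPM). Dcn, a proteoglycan of connective tissue, was 69.4-fold lower (4.44 ± 1.44 against 308 ± 258 CPM), and Pifo, a gene of ciliated cells, was 56.7-fold lower (0.586 ± 0.12 against 33.4 ± 14.4 CPM). Of 29361 genes tested, edgeR called 239 higher and 491 lower at an adjusted p of 0.05, of which 184 and 455 changed at least 2-fold. The count of higher genes was 151 without eGFP/tdTomato replicate 1, 152 without eGFP replicate 2, 475 without eGFP replicate 3, 103 without eGFP/tdTomato replicate 3, 108 without eGFP replicate 5 and 127 without eGFP/tdTomato replicate 5, and the count of lower genes was 323 without eGFP/tdTomato replicate 5. Without eGFP replicate 1, the library with the most reads outside genes, 193 genes were higher and 656 lower.

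Beside Olig2, Enpp6 and Chst7, the 10 genes that rose most, each with every eGFP/tdTomato library above every eGFP library, were Gpr17, Hapln1, Mag, Sox10, Vxn, Sez6l and Lrtm2, with log2 fold changes from 2.94 ± 0.45 (Lrtm2) to 3.66 ± 0.65 (Gpr17). Gpr17, a receptor of committed oligodendrocyte precursors, rose 12.7-fold to 26.7 ± 17.3 CPM, Hapln1, a link protein of hyaluronan matrix, rose 8.72-fold, and Mag, an adhesion protein of myelin, rose 8.65-fold. Mag was at 3.74 and Lrtm2 at 3.58 without eGFP replicate 3. Gpr17, Mag and Sox10 were not called when the 3 libraries numbered 5 were left out (adjusted p = 0.0873, 0.071 and 0.0919). The 10 genes that fell most, again with no overlap of the libraries, were Wfdc17, Cbr2, Dcn, Ccl11, Fcna, Pifo, Lum, Lyz2, Fam216b and Tmem212, with log2 fold changes from −7.17 ± 1.00 to −5.41 ± 0.68. Several rested on 1 library with a high level: the values were −5.87 for Wfdc17, −5.10 for Cbr2, −4.44 for Fcna and −4.28 for Lyz2 without eGFP replicate 5, and −5.38 for Dcn and −5.01 for Ccl11 without eGFP replicate 2. Without a library of the other fraction, Ccl11 was at −7.05 and Lum at −6.64 (eGFP/tdTomato replicate 2), and Cbr2 at −7.44 (eGFP/tdTomato replicate 5). Limma-voom did not call Wfdc17, Cbr2, Ccl11 or Fcna (adjusted p = 0.151, 0.173, 0.37 and 0.122).

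Some genes of each oligodendrocyte list were higher with both reporters. Of 28 myelinating oligodendrocyte genes, 12 rose and 1 fell (19 and 2 adjusted over the list alone), with a median log2 fold change of 1.52 (camera, adjusted p = 2.16e-13, or 0.0983 with an estimated correlation). Mog, a glycoprotein of the outer myelin surface, rose 7.57-fold (2.92 ± 0.43, adjusted p = 0.00121). Of 20 differentiating oligodendrocyte genes, 6 rose and 1 fell (14 and 1 over the list alone; median 0.95, adjusted p = 9.71e-12, or 0.0911 with an estimated correlation), among them Bcas1 at 5.46-fold. The member that fell in each list, named after its values were seen, was Enpp2 (−1.09 ± 0.18) and Tmem163 (−1.64 ± 0.37). Of 20 oligodendrocyte progenitor genes, 4 rose and none fell (9 and 0 over the list alone; median 0.71, adjusted p = 5.56e-06, or 0.112 with an estimated correlation). Those called were Olig1, Sox10, Lims2 and Kcnip3, while the progenitor markers Pdgfra and Cspg4 were not called. Olig1, a partner of Olig2, was at 1.86 ± 0.42 (adjusted p = 0.0253), and lost its call without eGFP replicate 2 (0.105), eGFP/tdTomato replicate 3 (0.0881), eGFP replicate 5 (0.116) or eGFP/tdTomato replicate 5 (0.0844). In summed CPM the myelinating and differentiating lists stayed far below the tdTomato fraction. The myelinating list was at 3050 ± 882 with both reporters, 1720 ± 326 in the eGFP fraction and 148000 ± 26700 in the tdTomato fraction. The differentiating list was at 1330 ± 244, 779 ± 109 and 24200 ± 5380 in the same order. The sum of the progenitor list was above the tdTomato fraction, at 4800 ± 534, 2920 ± 630 and 3160 ± 497. A sum is set by its most abundant members. Member by member, 2 of the 20 progenitor genes were higher and 11 lower than in the tdTomato fraction, with a median log2 fold change of −1.11.

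Astrocyte genes lay moderately higher in the eGFP/tdTomato than in the eGFP fraction as a list, with 3 of 32 called. The pan-astrocyte list summed to 101000 ± 9650 against 75300 ± 16900 CPM, and its median log2 fold change was 0.72 (adjusted p = 2.79e-18, or 0.103 with an estimated correlation). Part of the difference in sums came from scaling. The sum was 54300 in eGFP replicate 1, whose TMM factor of 1.443 lowers its levels. In the other eGFP libraries it was 73000 to 95300, with factors of 0.954 to 1.151. Acsbg1, Gjb6 and Slc7a10 rose and no member fell (18 and 0 of 32 adjusted over the list alone). Acsbg1, an acyl-CoA synthetase, rose 2.91-fold (1850 ± 263 against 635 ± 245 CPM, adjusted p = 0.00369), but the call was lost without the 3 libraries numbered 5 (0.0838). Gjb6, a connexin, rose 2.78-fold (adjusted p = 0.0308) and was not called without eGFP replicate 1 (0.066), eGFP/tdTomato replicates 1 (0.102), 3 (0.117) or 5 (0.0748), or eGFP replicate 5 (0.187). Slc7a10, a serine transporter, was barely called (adjusted p = 0.0481). It lost its call without eGFP replicate 2 (0.123) or 5 (0.243), without eGFP/tdTomato replicate 1 (0.0749), 2 (0.0647), 3 (0.234) or 5 (0.133), and without tdTomato replicate 1 (0.0744), 2 (0.0722), 3 (0.0557) or 5 (0.0559). Of 12 genes of grey matter astrocytes, 3 rose (12 over the list alone; median 0.94, adjusted p = 3.83e-15, or 0.0555 with an estimated correlation), with Gpc5, a glypican, at 2.74-fold, beside Slc7a10 and Slco1c1, a thyroid hormone and organic anion carrier. White matter astrocyte genes went both ways: Igfbp2, an IGF-binding protein, rose 3.55-fold, and Nes, the intermediate filament nestin, fell 5.62-fold, with 2 and 3 of 12 changed over the list alone, and Igfbp2 was not called without the 3 libraries numbered 5 (0.0825). That list's median was 0.08, its mean −0.06 and its camera direction down (adjusted p = 0.635). None of the 18 genes of transmitter uptake and ion transport passed over all genes, 12 were higher and 1 lower over the list alone, and the median was 0.79 (adjusted p = 5e-09, or 0.0983 with an estimated correlation).

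Most ependyma and macrophage markers and some fibroblast markers were higher in the eGFP fraction. All but 1 of the 14 ependyma genes fell (13 over the list alone; median −3.51, adjusted p = 7.92e-35, or 0.027 with an estimated correlation), and their sum was 421 ± 146 CPM in the eGFP against 51.9 ± 4.08 in the eGFP/tdTomato fraction. Dynlrb2, a dynein light chain gene, fell 18.8-fold and Cfap126, a cilium gene, fell 15.2-fold. Of 19 microglia and macrophage genes 11 fell (14 over the list alone; median −2.39, adjusted p = 1.12e-14, or 0.0942 with an estimated correlation). Lyz2, a lysozyme gene, fell 50.8-fold (3.57 ± 0.481 against 181 ± 233 CPM), and the complement genes C1qb and C1qc fell by 4.44 ± 0.77 and 4.16 ± 0.65 on the log2 scale. These values leaned on eGFP replicate 5, without which they were −4.28, −2.89 and −2.80, and limma-voom did not call C1qb (0.0514). Of 14 mural and fibroblast genes 5 fell (5 over the list alone; median −0.57, adjusted p = 3.42e-08, or 0.0654 with an estimated correlation), with Col3a1, a fibrillar collagen, at −4.80 ± 0.54, while the pericyte gene Rgs5 did not pass (−0.56 ± 0.43). Endothelium had 1 of 15 members lower, Itm2a at −1.21 ± 0.26 (2 over the list alone; median −0.64, adjusted p = 0.00513, or 0.18 with an estimated correlation). The Itm2a call was lost without eGFP replicate 2 (0.0765) or 5 (0.0692), or eGFP/tdTomato replicate 1 (0.0647), 3 (0.0675) or 5 (0.0746).

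**Figure D2:**
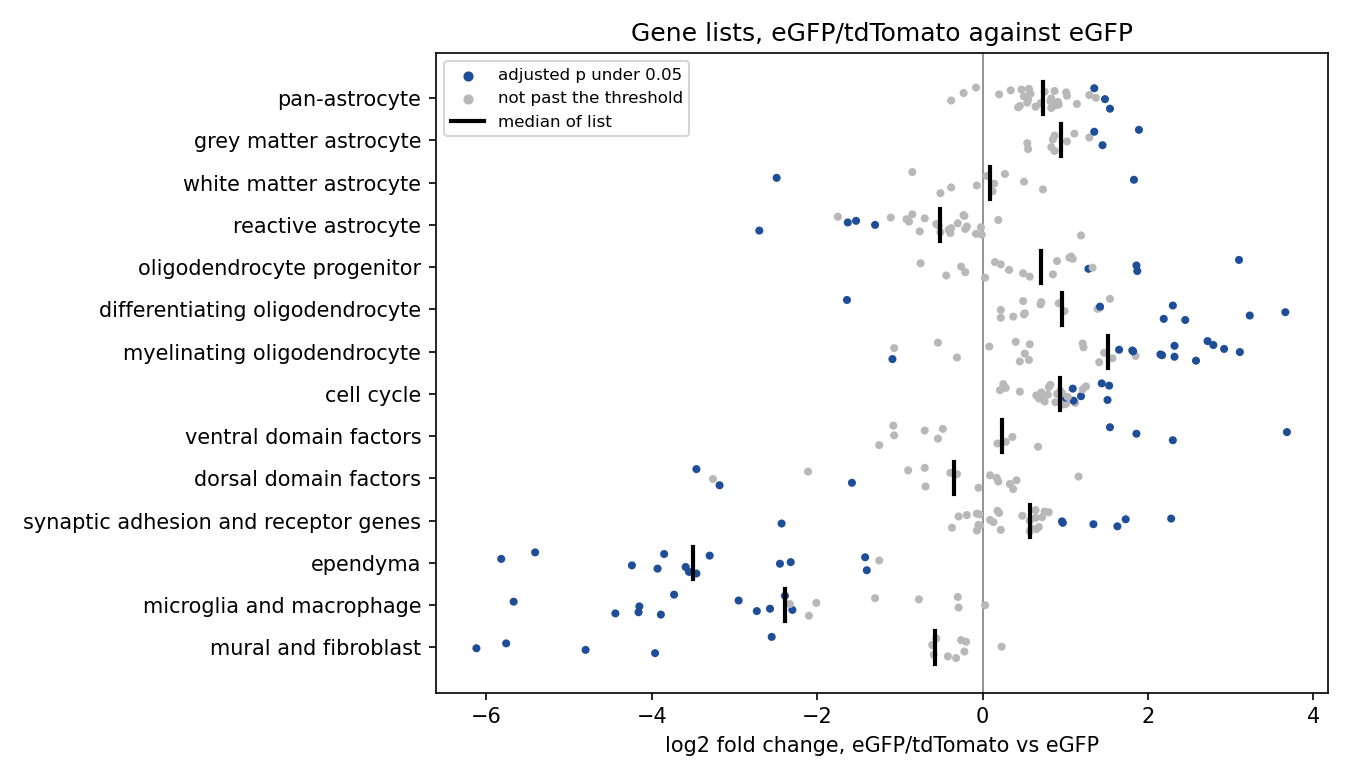
Log2 fold change of eGFP/tdTomato against eGFP for each member of 14 gene lists, with a point per gene, called genes (adjusted p under 0.05) in blue and the median of each list as a black line. The medians ran from −3.51 for ependyma to 1.52 for the myelinating oligodendrocyte list.

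Some cell cycle and position genes differed as well. Of 29 cell cycle genes 7 rose (23 over the list alone; median 0.94, adjusted p = 1.52e-19, or 0.0983 with an estimated correlation). Top2a, a topoisomerase of dividing cells, rose 2.88-fold (49.8 ± 8.77 against 17.3 ± 5.33 CPM), and Ube2c, a ubiquitin enzyme of mitosis, 2.72-fold. Top2a was not called without the 3 libraries numbered 1 (0.0731) or 5 (0.057). Among ventral domain factors, Nkx2-2, of the ventral progenitor domains and oligodendrocyte precursors, rose 4.94-fold (2.30 ± 0.31, adjusted p = 0.000555), and 4 of 14 rose and none fell (5 and 3 over the list alone; median 0.23, adjusted p = 0.137). Among dorsal domain factors, Zic4 fell by 3.46 ± 0.39 on the log2 scale (6.32 ± 1.21 against 69.4 ± 27.7 CPM), Lmx1a 9.08-fold and Msx1 3.00-fold, which were the 3 of 18 that fell (5 over the list alone; median −0.35, adjusted p = 0.00035, or 0.0813 with an estimated correlation).

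Receptor and matrix genes changed member by member. Of 31 synaptic adhesion and receptor genes 6 rose and 1 fell (12 and 1 over the list alone; median 0.57, adjusted p = 2.01e-06, or 0.218 with an estimated correlation). The metabotropic glutamate receptor genes Grm5 and Grm3 rose 4.84-fold and 3.31-fold, and Gria1, an AMPA receptor subunit, fell 5.40-fold (67.2 ± 16.3 against 363 ± 124 CPM). Of the 14 matrix proteoglycan genes, Hapln1 alone rose over all genes (5 over the list alone; median 0.64, adjusted p = 0.000134, or 0.0698 with an estimated correlation). Of the 21 synapse-regulating secreted factors, Gpc5 alone rose (3 over the list alone; median 0.30, adjusted p = 0.00694, or 0.306 with an estimated correlation), and that list was not called without eGFP replicate 1 (0.2). Of 27 reactive astrocyte genes 4 fell (6 over the list alone; median −0.51, adjusted p = 5.69e-09, or 0.0654 with an estimated correlation), with Cp, ceruloplasmin, at −2.70 ± 0.33. Of the 4, Ptx3 and S1pr3 were not called without eGFP replicate 2 (0.0576 and 0.0588), and 1 to 6 were called with 1 library left out at a time. The heat shock gene Hspa1a fell 13.1-fold and was the 1 of 22 immediate early and dissociation stress genes to pass (2 over the list alone; median −0.23, adjusted p = 0.000754, or 0.306 with an estimated correlation). Of 21 neuron genes, the RNA-binding protein gene Elavl3 rose (1.37 ± 0.26) and the ubiquitin hydrolase gene Uchl1 fell (−1.34 ± 0.23; 1 and 3 over the list alone; median −0.17, adjusted p = 0.0618), calls that were lost without the 3 libraries numbered 2 (0.118 and 0.0637) or 5 (0.129 and 0.0591), and none of the 8 motor neuron genes passed (0 over the list alone; median −0.81, adjusted p = 0.285).

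The numbers of list members called depended on the libraries. With each of the 12 left out in turn, 10 to 14 myelinating, 5 to 9 differentiating, 2 to 6 progenitor, 3 to 11 cell cycle, 1 to 14 pan-astrocyte, 1 to 7 grey matter, 0 to 9 transmitter and ion transport, 2 to 5 ventral and 4 to 7 synaptic genes were called higher. Called lower were 10 to 13 ependyma, 6 to 12 microglia and macrophage and 4 to 5 mural and fibroblast genes, and the 3 dorsal genes stayed. Without the 3 libraries numbered 5, 7 myelinating, 0 progenitor, 0 pan-astrocyte and 1 cell cycle gene were higher and 3 microglia and macrophage genes lower.

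The second comparison asks what separates cells with both reporters from cells of the tdTomato fraction. Astrocyte genes were far higher and myelin genes far lower in the eGFP/tdTomato fraction. Gja1, the main astrocyte connexin, was 693-fold higher (6030 ± 684 against 8.70 ± 2.02 CPM, SD, n = 4 each), and Aqp4, the astrocyte water channel, 427-fold (11200 ± 904 against 26.4 ± 5.50 CPM). Mag was 86.5-fold lower (103 ± 49.1 against 8900 ± 2190 CPM) and Mog 89.6-fold lower. edgeR called 4935 genes higher and 3628 lower. The count of lower genes was 5452 without eGFP replicate 1, although that library belongs to neither fraction, and 57.6% of the calls were higher, or 44.2% without that library, 43.5% without eGFP/tdTomato replicate 3, 44.7% without eGFP replicate 5 and 45.8% with at least 1 CPM in 4 libraries. The median log2 fold change of all genes was 0.70. Over the alternatives it ran from 0.07 (protein-coding genes of at least 1 mean CPM) to 0.97 (without tdTomato replicate 5), with 0.23 under the covariate for reads outside genes. The median of the 10146 genes with a mean of at least 10 CPM was −0.13.

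The 10 genes that rose most were Gja1, Gjb6, Slc39a12, Agt, Nat8, Aqp4, Sparcl1, Acsbg1, Pla2g7 and Mlc1, with every eGFP/tdTomato library above every tdTomato library. Nat8 had 2 counts in the tdTomato libraries against 1178, a ratio of 597 (95% exact interval 165 to 4940, counting error only). Its log2 fold change was 11.13 without tdTomato replicate 5. The others ran from 8.60 ± 0.46 (Mlc1) to 9.44 ± 0.30 (Gja1) on the log2 scale. Among the 10 that fell most were the myelin and oligodendrocyte genes Opalin, Mog, Ermn, Mag, Cldn11, Tmem125, Mobp and Gjb1 and the apolipoprotein gene Apod, from −6.51 ± 0.32 to −6.27 ± 0.47. By list, 30 of 32 pan-astrocyte genes rose (31 over the list alone; median 6.68, adjusted p = 1.58e-32, or 0.0484 with an estimated correlation). All 20 differentiating genes fell (20 over the list alone; median −4.76, adjusted p = 6.33e-31, or 0.0232 with an estimated correlation), and 27 of 28 myelinating genes fell (27 over the list alone; median −5.74, adjusted p = 9.79e-42, or 0.0232 with an estimated correlation). The exception was Aspa, an enzyme of acetylaspartate breakdown (−0.25 ± 0.17, adjusted p = 0.298, or 0.0304 without eGFP replicate 1). The progenitor list was mixed, with 2 members higher and 11 lower (3 and 11 over the list alone; median −1.11, adjusted p = 5.6e-06, or 0.127 with an estimated correlation). Ednrb, an endothelin receptor, rose by 5.54 ± 0.33, Sox10 fell by 5.27 ± 0.57, and Olig1 did not pass (−0.65 ± 0.41, adjusted p = 0.245).

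Other astrocyte gene groups rose with them. Of 18 transmitter and ion transport genes 16 rose (17 over the list alone; median 4.64, adjusted p = 6.41e-17, or 0.045 with an estimated correlation), such as the GABA transporter Slc6a11 at 305-fold. Of 12 grey matter genes 11 rose (11 over the list alone; median 5.17, adjusted p = 6.59e-12, or 0.0464 with an estimated correlation), and of 12 white matter genes 9 (9 over the list alone; median 5.73, adjusted p = 2.79e-09, or 0.0652 with an estimated correlation), with Gfap, the astrocyte intermediate filament, at 153-fold. Of 27 reactive astrocyte genes 21 rose (21 higher and 1 lower over the list alone; median 4.26, adjusted p = 4.46e-10, or 0.045 with an estimated correlation). Of the 21 synapse-regulating secreted factors 14 rose and 2 fell (16 and 2 over the list alone; median 3.11, adjusted p = 1.31e-08, or 0.0652 with an estimated correlation), with Thbs2, a thrombospondin, at 47.4-fold. Immediate early and stress genes were also higher, 17 of 22 with 1 lower (17 and 1 over the list alone; median 3.40, adjusted p = 1.61e-10, or 0.0685 with an estimated correlation), with Junb at 45.4-fold. Dorsal factors rose in 11 of 18 cases with 1 lower (12 and 1 over the list alone; median 3.10, adjusted p = 0.000583, or 0.0652 with an estimated correlation), including Zic1 at 99.3-fold, while ventral factors split into 7 higher and 4 lower (7 and 4 over the list alone; median 1.90, adjusted p = 0.165), with Reln 97.9-fold higher and Nkx6-2 33.8-fold lower.

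Lists for further cell types and for cell division followed in the same comparison. Of 14 mural and fibroblast genes 10 rose (11 over the list alone; median 1.87, adjusted p = 0.00665, or 0.216 with an estimated correlation), with Col1a2 99.0-fold higher. Of 14 ependyma genes 11 rose (11 over the list alone; median 2.14, adjusted p = 0.0109, or 0.484 with an estimated correlation), with Rarres2 29.7-fold higher. Of the 14, 4 had at least 5 CPM in the eGFP/tdTomato and 1 in the tdTomato fraction. With 1 library left out at a time, 5 to 11 mural and fibroblast and 8 to 12 ependyma genes were called higher. The 1106 olfactory and vomeronasal receptor genes tested, 34 of them called higher, had a median of 1.67 in this comparison. The neuron list had 3 members higher and 9 lower (3 and 9 over the list alone; median −0.39, adjusted p = 0.00817, or 0.162 with an estimated correlation), with Elavl3 57.4-fold lower. Microglia and macrophage genes had 2 members higher (2 over the list alone), a median of −0.09, a mean of 0.19 and a camera direction of down (adjusted p = 0.845). The synaptic list had 13 members higher and 13 lower (14 and 13 over the list alone), with a median of −0.18, a mean of 0.83 and a camera direction of up (adjusted p = 0.864). Cell cycle genes were close to the tdTomato level, with Cdc20, Ube2c and Pcna lower over all genes, 0 over the list alone and a median of −0.25 (adjusted p = 0.0109, or 0.627 with an estimated correlation). With 1 library left out at a time, 0 to 7 cell cycle genes were called lower. Cdc20, an activator of mitotic exit, was at −0.78 ± 0.23 (adjusted p = 0.0177, or 0.0928 without tdTomato replicate 2).

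The third comparison sets the eGFP fraction against the tdTomato fraction, the astrocyte against the oligodendrocyte lineage reporter. Astrocyte, ependymal, fibroblast and macrophage genes were higher in the eGFP fraction and oligodendrocyte and cell cycle genes lower. Gja1 was 475-fold higher (4130 ± 813 against 8.70 ± 2.02 CPM, SD, n = 4 each) and Prelp, a matrix protein gene, 541-fold higher. Enpp6 was 454-fold lower (4.58 ± 2.00 against 2080 ± 442 CPM) and Mag 748-fold lower. edgeR called 5975 genes higher and 4372 lower. The median of all genes was 0.79 and ran from 0.09 (with the covariate for reads outside genes) to 1.07 (without tdTomato replicate 5) over the alternatives. That of the 10146 genes with a mean of at least 10 CPM was −0.26. Which direction had more calls depended on the libraries and the filter: 57.7% were higher, but 48.4% without eGFP replicate 1 (4781 higher and 5091 lower), 46.9% without eGFP/tdTomato replicate 3 (4965 and 5625), 47.8% without eGFP replicate 5 (4359 and 4768) and 49.4% with at least 1 CPM in 4 libraries (5302 and 5441).

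Named by size, the genes that rose most in the eGFP fraction were Wfdc17, Pifo, Prelp, C1qtnf3 and Gja1, and among those that fell most were Mag, Mog, Mir219a-2 and Gpr17, with no overlap of the 4 and 4 libraries. Wfdc17 and Pifo had 4 counts in all tdTomato libraries together, all in tdTomato replicate 5 for Pifo, so their fold changes are loose. Without tdTomato replicate 5, Wfdc17 was at 13.08 and Pifo at 12.74 on the log2 scale, against 9.99 ± 1.24 and 9.66 ± 0.65 with it, and without eGFP replicate 5 Wfdc17 was at 8.44. C1qtnf3 was at 10.46 without tdTomato replicate 5 and at 9.94 by limma-voom (8.90 ± 0.64 with edgeR), and Gpr17 was at −9.61 by limma-voom (−9.02 ± 0.80). Mag fell by 9.55 ± 0.72 on the log2 scale (−10.18 without eGFP replicate 3) and Mog by 9.41 ± 0.56 (−10.06 without eGFP replicate 5). Mir219a-2, a microRNA locus, fell by 9.24 ± 0.45 (−10.11 without eGFP replicate 3). Of 28 myelinating genes all fell (28 over the list alone; median −7.51, adjusted p = 3.81e-36, or 0.0289 with an estimated correlation), as did all 20 differentiating genes (20 over the list alone; median −4.80, adjusted p = 1.17e-27, or 0.0289 with an estimated correlation). Of the progenitor genes 1 rose and 14 fell (2 and 14 over the list alone; median −2.08, adjusted p = 3.29e-07, or 0.0793 with an estimated correlation). The pan-astrocyte list had 29 of 32 members higher and 1 lower (29 and 1 over the list alone; median 6.02, adjusted p = 1.25e-25, or 0.0687 with an estimated correlation). Of 29 cell cycle genes 23 fell (24 over the list alone; median −1.22, adjusted p = 1.44e-10, or 0.172 with an estimated correlation), with Top2a 3.81-fold lower.

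Ependyma, macrophage and fibroblast genes were again higher in the eGFP fraction, and the olfactory and vomeronasal receptor genes had a median of 1.92. All 14 ependyma genes rose (14 over the list alone; median 5.54, adjusted p = 2.73e-08, or 0.0955 with an estimated correlation), with Dynlrb2 108-fold higher. Macrophage and microglia genes rose in 15 of 19 cases (15 over the list alone; median 2.32, adjusted p = 0.000615, or 0.333 with an estimated correlation), with Lyz2 at 7.19 ± 0.86, or 5.55 without eGFP replicate 5. Mural and fibroblast genes rose in 11 of 14 cases (13 over the list alone; median 3.75, adjusted p = 2.77e-05, or 0.0707 with an estimated correlation), with Dcn at 7.61 ± 0.70, or 6.88 without eGFP replicate 2. Endothelial genes rose in 10 of 15 cases and 1 fell (12 and 1 over the list alone; median 1.76, adjusted p = 0.0302, or 0.252 with an estimated correlation), and this list call was lost with a covariate for reads outside genes (0.0505) and with TMM factors from abundant genes (0.0516). With 1 library left out at a time, 5 to 12 endothelial genes were called higher. The sum of the ependyma list was 421 ± 146 CPM in the eGFP fraction and 14.4 ± 3.42 in the tdTomato fraction. For the neuron list, 4 members were higher and 8 lower (6 and 8 over the list alone), the median was 0.20, the mean −0.26 and the camera direction down (adjusted p = 0.0903). For the synaptic list, 13 were higher and 15 lower (13 and 16 over the list alone), the median was −0.88, the mean 0.40 and the direction down (adjusted p = 0.419). Reactive astrocyte genes rose in 22 of 27 cases (24 over the list alone; median 4.65, adjusted p = 1.91e-12, or 0.0289 with an estimated correlation), and immediate early and stress genes in 21 of 22 (21 over the list alone; median 3.41, adjusted p = 3.92e-14, or 0.0531 with an estimated correlation).

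Over the 31 lists, camera with its preset correlation called 21, 22 and 23 in these comparisons, and with an estimated correlation 1, 7 and 3. The calls that held were ependyma against the eGFP fraction, then pan-astrocyte, differentiating, myelinating, grey matter, transmitter and ion transport, BMP and reactive astrocyte against the tdTomato fraction, and differentiating, myelinating and reactive astrocyte between the eGFP and tdTomato fractions.

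Some genes set the eGFP/tdTomato fraction apart from both other fractions. Chst7 lay above the eGFP fraction by 3.32 ± 0.39 and above the tdTomato fraction by 3.94 ± 0.40 on the log2 scale. Hapln1 was 8.72-fold and 72.8-fold higher (28.6 ± 5.88 CPM with both reporters, against 3.28 ± 0.444 and 0.376 ± 0.355, SD, n = 4), and Grm5, a metabotropic glutamate receptor, was 4.84-fold and 5.99-fold higher (113 ± 29.2 CPM against 23.3 ± 6.45 and 18.9 ± 4.49). Apod, a lipocalin, was 36.3-fold and 80.9-fold lower (9.65 ± 1.99 CPM against 350 ± 317 and 782 ± 199), and Lpar1, a lysophosphatidic acid receptor, 5.35-fold and 29.6-fold lower. In all, 85 genes were higher and 62 lower than in both fractions, each at least 2-fold. Both comparisons share the eGFP/tdTomato libraries: 10 simulations with no effect gave 0 and 0 genes, the product of the list sizes over the genes tested was 27.0 and 37.1, and with the 4 shared libraries divided between the comparisons, in 6 arrangements, 15 to 62 genes were higher and 17 to 28 lower. The simulations gave every fraction the same mean per gene, so few calls were possible in either comparison. They cannot show how many genes the sharing adds where fractions differ. The higher count was 42 without eGFP replicate 1, 198 without eGFP replicate 3, 33 without eGFP/tdTomato replicate 3, 29 without eGFP replicate 5 and 45 without eGFP/tdTomato replicate 5, and the lower count was 97 without eGFP replicate 1.

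**Figure D3:**
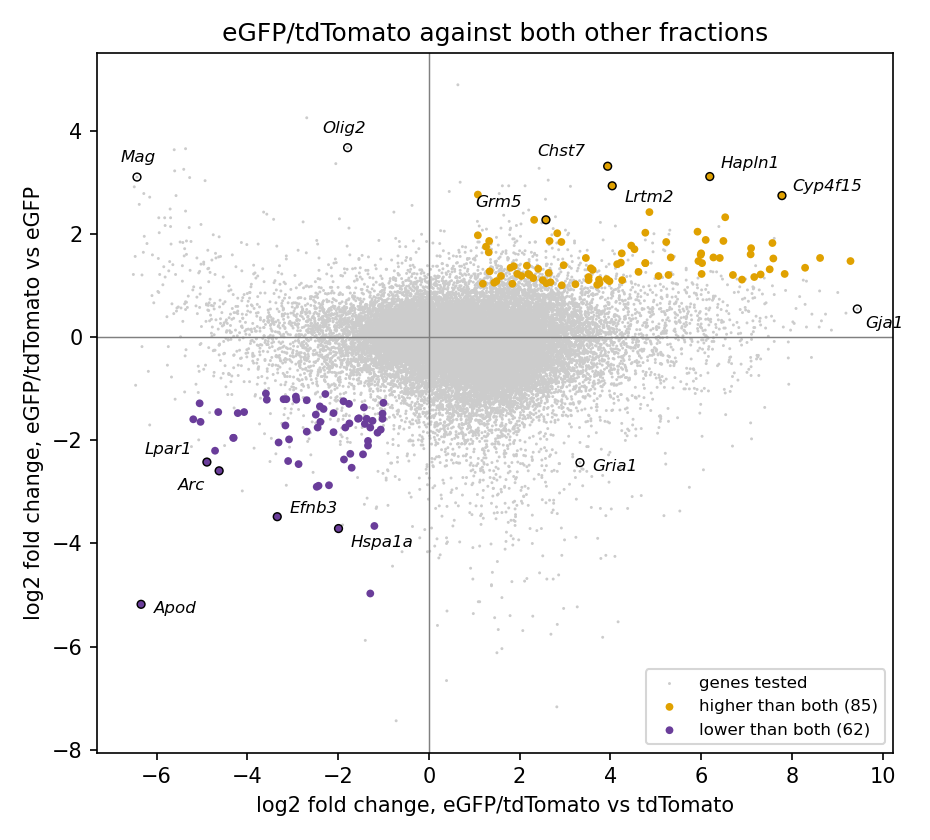
Log2 fold change of eGFP/tdTomato against tdTomato (x axis) and against eGFP (y axis), with a point per gene, the 85 genes higher than both in orange and the 62 lower than both in purple. Chst7 lay at 3.94 and 3.32, and Apod at −6.34 and −5.18.

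The 15 genes named above both, under a minimum of 10 CPM, were Chst7, Hapln1, Lrtm2, Cyp4f15, Slc25a34, AW011738, Grm5, Pla2g3, Slc13a3, Inka2, Slco1c1, Trhr, Kcnip3, Cth and Hes5, with every eGFP/tdTomato library above every other library. Kcnip3, a calcium sensor, was 3.65-fold and 6.32-fold higher, Pla2g3, a secreted phospholipase, 4.15-fold and 60.6-fold, and Cth, an enzyme of cysteine synthesis, 3.60-fold and 37.5-fold. Without the 3 libraries numbered 5, Kcnip3 was not called against the eGFP fraction (0.0735), nor was Slc13a3 (0.139, and 0.0539 without those numbered 2). Hes5, a Notch target, was 3.59-fold and 7.55-fold higher (103 ± 18.4 CPM with both reporters), but the call against the eGFP fraction was lost without eGFP replicate 5 (adjusted p = 0.0663), as was that of Inka2 (0.0533). Slc25a34, Slco1c1 and Trhr were weaker against the eGFP fraction. Slc25a34, a mitochondrial carrier, lost its call without eGFP replicate 1 (0.0643), 2 (0.0939) or 5 (0.0972), or eGFP/tdTomato replicate 2 (0.059), 3 (0.0873) or 5 (0.083). Slco1c1 lost it without eGFP replicate 1 (0.114), 3 (0.0562) or 5 (0.183), eGFP/tdTomato replicate 1 (0.0968), 3 (0.175) or 5 (0.0508), or tdTomato replicate 1 (0.0531). Trhr, a receptor for thyrotropin-releasing hormone, lost it without eGFP replicate 1 (0.0817) or 5 (0.16), or eGFP/tdTomato replicate 1 (0.117), 2 (0.059), 3 (0.103) or 5 (0.0565). Without eGFP replicate 3, log2 fold changes against the eGFP fraction were 3.58 for Lrtm2, 3.17 for Slc25a34 and 2.64 for Inka2. Without tdTomato replicate 5, those against the tdTomato fraction were 7.18 for Slc25a34 and 7.30 for Trhr. From the fixed lists, the higher set held 3 pan-astrocyte, 3 grey matter, 1 white matter, 1 progenitor, 1 ventral, 4 synaptic, 1 synapse-regulating, 1 matrix, 2 Notch and 3 Wnt genes, counting a gene in each list that holds it. With 1 library left out at a time, 1 to 13 pan-astrocyte, 1 to 6 grey matter, 0 to 1 ventral, 1 to 2 synapse-regulating, 0 to 4 Notch and 0 to 4 Wnt genes were above both, and the other counts named here stayed. Some lists with no gene in the set gained members, with 0 to 8 transmitter and ion transport, 0 to 3 complement and phagocytosis and 0 to 2 Hedgehog genes. The Wnt genes Fzd9, Fzd10 and Lgr6 were all lost without eGFP replicate 1 or 5 or eGFP/tdTomato replicate 3 or 5, and the Notch gene Heyl was not called against the eGFP fraction in 13 of 29 settings.

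Named below both, among genes with at least 10 CPM in the higher fraction of each comparison and no overlap of the libraries, were Apod, Efnb3, Arc, Mmp2, Lpar1, Hspa1a, Bcat1 and Synm. Efnb3, an ephrin, was 11.1-fold and 10.1-fold lower (32.7 ± 18.4 CPM against 364 ± 318 and 332 ± 167), Arc, a neuronal activity gene, 6.04-fold and 24.6-fold, and Synm, the intermediate filament synemin, 5.18-fold and 3.65-fold. In the eGFP libraries numbered 1, 2, 3 and 5, Apod was at 242, 806, 75.4 and 277 CPM and Mmp2 at 17.7, 48.7, 6.51 and 24.2, in the order of the fibroblast marker Dcn at 216, 673, 67.3 and 277. Against the eGFP fraction, Apod was at −4.34 and Mmp2 at −2.27 without eGFP replicate 2, and Efnb3 at −2.65 without eGFP replicate 3. Against the tdTomato fraction, Efnb3 was at −3.96 without eGFP/tdTomato replicate 3. Efnb3 and Mmp2 were not called against the eGFP fraction without the 3 libraries numbered 5 (adjusted p = 0.0564 and 0.0558).

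**Figure D4:**
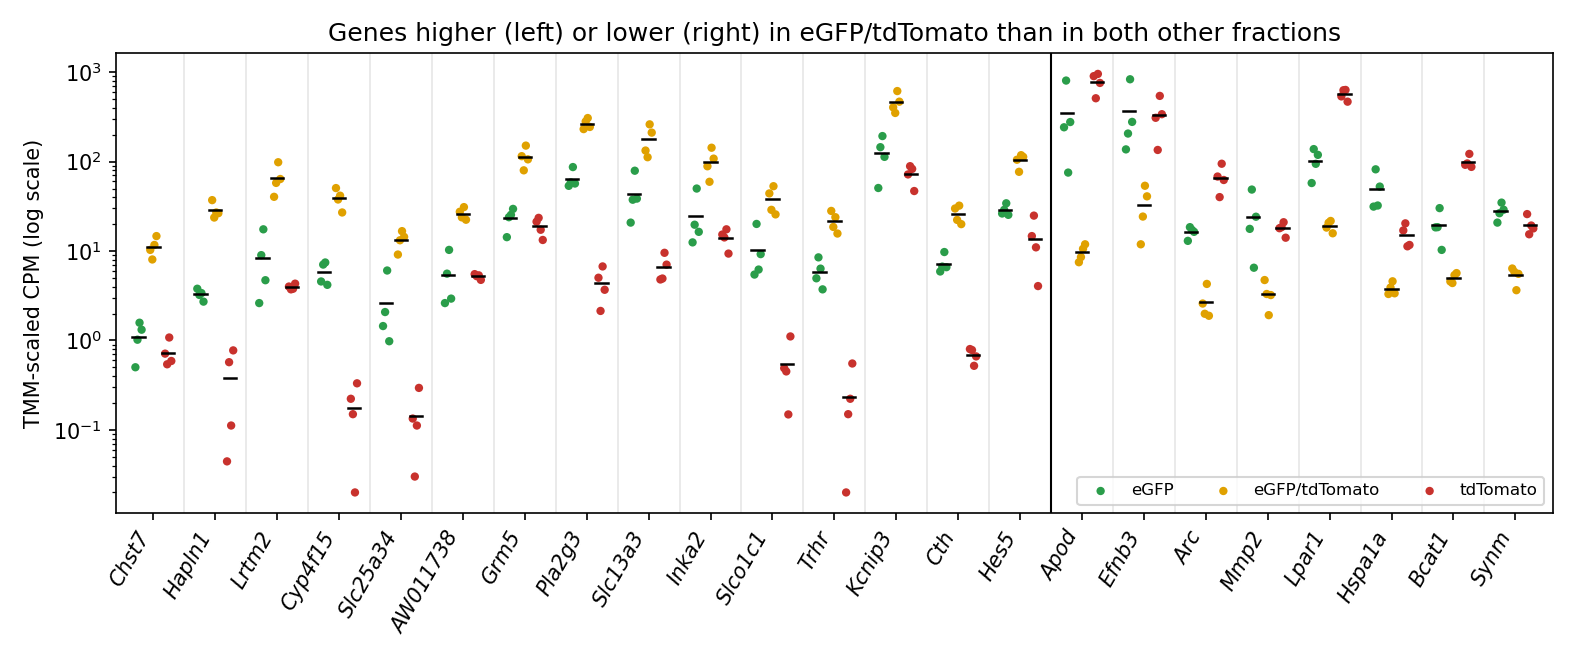
Level of the 15 genes named as higher and the 8 named as lower than in both other fractions, in TMM-scaled CPM on a log axis, with a point per library (4 per fraction). Every eGFP/tdTomato library lay above or below all other libraries for each gene, and libraries with 0 counts are drawn at the bottom of the axis.

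The level of the eGFP/tdTomato fraction was placed between the others as a share. With 0% at the eGFP level and 100% at the tdTomato level of the mean CPM, the median share was 0.97% for 27 myelinating genes, 1.97% for 20 differentiating genes and 2.18% for 12 progenitor genes, whose means over the 4 replicate numbers were 1.00 ± 0.33%, 1.99 ± 0.96% and 4.80 ± 4.07% (SD, n = 4). The differences between these lists were 0.75 to 1.5 times their SD over the replicate numbers, and the progenitor list was not told apart from the others. The differentiating share was above the myelinating share in every replicate number. In the order 1, 2, 3 and 5 these shares were 0.88, 1.67, 2.24 and 3.16% against 0.53, 1.04, 1.11 and 1.31%. Olig2 was at 27.23% (28.26 ± 10.46% over the replicate numbers) and Olig1 at 55.89% (57.45 ± 19.44%), while Sox10, a transcription factor of the whole oligodendrocyte lineage, was at 2.30% (2.30 ± 1.69%). The progenitor markers Pdgfra and Cspg4 were at −2.75% (−3.07 ± 2.99%) and 10.41% (10.61 ± 1.11%). The share was −53.92% for 28 pan-astrocyte genes (−69.65 ± 46.43%), a level beyond the eGFP fraction, where Gja1 was at −46.02% and Gfap at 23.20%. Without the 3 libraries numbered 1, the progenitor share was 5.43%, and without those numbered 5 it was 1.41%. The pan-astrocyte share ran from −72.40% to −38.01% when the libraries of 1 number were left out.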

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

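Among these tests, the splits of the 8 libraries for single comparisons and the test of a mixture for all genes were planned before the data were examined, while the splits for genes outside both fractions and the tests on simulated mixtures, myelin, Olig2, other cell types, background reads and dilution were chosen only after the result was seen.

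The real assignment of libraries called the most genes in each comparison. Every other split mixes sorted fractions within a group, which raises the spread, so few calls there were set by the design. With 35 splits the real one cannot be rarer than 1 in 35, and no conclusion on chance is drawn. Of the 35 splits of 8 libraries into 4 and 4, 1, the real one, called as many genes: 730 against the eGFP fraction (highest other split 1), 8563 against the tdTomato fraction (highest other 0) and 10347 between the eGFP and tdTomato fractions (highest other 0). Of 100 drawn splits of the 12 libraries, 1, the real one, gave 85 genes above both other groups and 1 gave 62 below both (highest other 0 for each).

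Libraries of the eGFP/tdTomato fraction held transcripts of both other fractions, which doublets or sort spill-over could bring. A mixture allows no gene outside the range of its parts, and 85 genes lay above both (15 to 62 with the shared libraries divided between the comparisons), against at most 1, 5 and 6 in 10 simulated mixtures each with 1, 10 and 50% tdTomato, so a mixture of the fractions as sequenced is excluded as the whole cause, and dilution of the eGFP fraction by about 1.65-fold would not raise Chst7 by 3.32 on the log2 scale. For Olig2 a mixture of the fractions as sequenced is excluded as well: its share between the fractions exceeded that of the myelinating list by 27.26 points (SD 10.14, n = 4) and that of Sox10 by 25.95 points (SD 8.96). These tests take each fraction as a whole. Doublets or spill-over from a part of a fraction, unlike the whole in its transcripts, are not excluded for Olig2 or for the 85 genes. The cells were also sorted on the Olig2 reporter. For myelin and differentiation genes a mixture with a small share of tdTomato RNA stays open (median shares of 0.97 and 1.97%), since the shares of these lists differed by 0.99 points (SD 0.66) and both lay above 0 in every replicate number. These are shares of RNA, from which a number of cells cannot be read. A mixture gives both lists 1 share, whereas the differentiating share was the higher in every replicate number, so a mixture was not shown to be the whole cause. That cells with both reporters express these genes at a low level themselves is the other open explanation, and it was not tested.

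Many ependyma and macrophage genes and some fibroblast genes were higher in the eGFP than in the eGFP/tdTomato fraction, and other cell types in the eGFP fraction are a candidate explanation. Of the tested members, 13 of 14 ependyma genes (median −3.51) and 11 of 19 microglia and macrophage genes (median −2.39, with P2ry12, Ptprc and Laptm5 among those not lower) were lower with both reporters, which are the values this needs, while for mural and fibroblast genes, 5 of 14 lower with a median of −0.57, the explanation stays undecided. Among the most abundant were Dcn (308 ± 258 CPM), Lyz2 (181 ± 233) and Dynlrb2 (46.2 ± 17.9) in the eGFP fraction, whereas Col1a2 was at 476 ± 114 there and 408 ± 91.1 with both reporters. In the eGFP/tdTomato fraction 4 of 14 ependyma, 5 of 19 microglia and macrophage and 5 of 15 mural and fibroblast genes still had at least 5 CPM, and 0, 3 and 0 members belonged to another list. Sorting out cells with CD24 (ependyma), CD45 (macrophages) and PDGFRB (mural cells and fibroblasts) could test this. Ptprc, the gene of CD45, and Pdgfrb were themselves not called lower with both reporters. Expression of the same genes by astrocytes with 1 reporter remained untested.

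Pan-astrocyte genes were higher with both reporters than in the eGFP fraction, with a median log2 fold change of 0.72 and 29 of 32 members positive. Background reads that shift the scaling are excluded as the whole cause, since the lowest median over other scaling, the covariate and the fit without eGFP replicate 1 was 0.47. A single dilution factor from other cells in the eGFP fraction would be 1.65-fold. It leaves 5 members over 2 SE from the median (1.6 expected if members were independent), with a range of −0.38 to 1.54. A single factor holds only if the other cells express no member of the list. Dilution by cells that express some members is therefore not excluded by this test. Dilution or background as a part of the rise stays open, as does a difference between the sorted astrocytes, which was not tested.

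Among 132 groups of 4 libraries, 7 had a library far from the others, where chance gives about 1 in 20 groups (6.6). Gja1 was at 2910 CPM in eGFP replicate 1 (4460 to 4600 in the others) and Zic4 at 28.4 (79.6 to 88.7). Both levels were lowered by that library's TMM factor of 1.443, against 0.954 to 1.151 in the other eGFP libraries. From genes of at least 10 mean CPM its factor was 1.045, so the Gja1 value is not read as a difference in astrocyte content. Aqp4 was at 34.6 CPM in tdTomato replicate 1 (22.9 to 24.3), where the erythrocyte list summed to 133 (30.5 to 39.4). The mural and fibroblast list summed to 10.6 CPM in tdTomato replicate 3 (21 to 21.5). Pifo was at 0.148 CPM in tdTomato replicate 5 and at 0 in the others. Dynlrb2 was at 2.07 CPM in eGFP/tdTomato replicate 5 (2.52 to 2.60). Outside the main measurement, eGFP replicate 1 had 2.006 reads outside genes per gene count (0.332 to 0.995 in the other libraries) and 3970 CPM on olfactory and vomeronasal receptor genes. Of 1106 such receptor genes tested, edgeR called 0 against the eGFP fraction (median −0.21, and 2921 of all genes had an unadjusted p under 0.05), 34 higher and 1 lower against the tdTomato fraction (median 1.67) and 74 higher and 1 lower between the eGFP and tdTomato fractions (median 1.92).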

How the results depend on the processing

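Tests with a covariate for reads outside genes, with the block and that covariate, with TMM factors from abundant genes and with protein-coding genes of at least 1 mean CPM were chosen only after the result was seen. No gene called in one direction was called in the other under any alternative. Of the results for named genes, 6071 kept their side of the threshold, 209 lost a call and 40 gained one. For the lists these were 812, 98 and 20.

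Against the eGFP fraction, 239 genes were higher and 491 lower. With upper quartile scaling 391 were higher, with the DESeq2 Wald test 549 (949 lower), with the covariate 520 and with protein-coding genes of at least 1 mean CPM 378. Above both other fractions were 85 genes, or 141 by limma-voom, and below both 62, or 105 by DESeq2. The cause was not tested.

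By its construction, glmTreat against a log2 fold change of 1 calls fewer genes: 32 higher and 188 lower against the eGFP fraction, 2746 and 1368 against the tdTomato fraction, 3379 and 1529 between the eGFP and tdTomato fractions, and 8 above and 14 below both.

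With the replicate number as a replicate block, 566 genes were higher against the eGFP fraction and 134 above both, and with the covariate as well 721 were higher and 831 lower. The libraries were not treated as paired in the tests, and only the spread of the interpolation shares was taken over libraries of the same number. The residuals of 12 pairs with the same number correlated from −0.23 to 0.60 (median 0.19, 8 over 0.1), against a median of −0.105 for 36 others, and the best match had the same number in 10 of 24 cases. The 4 Y-linked genes checked had at least 5387 counts in each library numbered 3 and at most 4 in the others. Male tissue was thus in all 3 fractions numbered 3 and in no other number, which ties these 3 fractions together. Xist, a transcript of female cells, was present there too (231 to 385 CPM, without TMM factors). Sex therefore differed between the numbers and was not a factor in the main fit. What the fractions of the other numbers share is not shown by these genes.

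Leaving out each library or replicate number gave 60 to 475 genes higher and 201 to 656 lower against the eGFP fraction, 2609 to 5452 lower against the tdTomato fraction, 18 to 198 above both and 23 to 97 below both, and the cause was not tested. The interpolation shares moved by less than their spread in each of the 9 alternatives run for them. Over all 64 combinations of 1 library per fraction, whatever its number, a check chosen after the result was seen, the share of Olig2 was at least 9.30%, that of Sox10 at most 7.40% and that of the myelinating list at most 2.07%.

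Depth itself was not varied. Without the filter on low counts 226 genes were higher and 525 lower against the eGFP fraction, and with at least 1 CPM in 4 libraries 334 and 679.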

Other observations

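The list tests below were fixed before the data were examined, and the counts of members with libraries left out were chosen only after the result was seen.

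Signalling lists changed little as a whole between the eGFP/tdTomato and eGFP fractions. Of 19 Notch genes 3 rose (4 over the list alone; median 0.12, adjusted p = 0.0537), among them the ligand gene Dll3 (1.52 ± 0.35), whose call was lost without eGFP replicate 2 (0.104) or 5 (0.0925), without eGFP/tdTomato replicate 2 (0.103) or 3 (0.0643), and by limma-voom (0.279). The 2 others were Hes5 and Heyl, and Heyl lost its call in 13 of 29 settings. With 1 library left out at a time, 0 to 5 Notch genes were called higher. Of 13 Hedgehog genes the inhibitor gene Hhip rose (0.99 ± 0.20) and the coreceptor gene Cdon fell 3.00-fold (3 and 1 over the list alone; median 0.12, adjusted p = 0.688), and the call of Hhip was lost without eGFP replicate 5 (0.141) or eGFP/tdTomato replicate 1 (0.0573) or 3 (0.142) and that of Cdon without the 3 libraries numbered 5 (0.0552). Of 24 BMP and TGF-beta genes Bmp4 rose 4.55-fold and Bmp2 fell 7.46-fold (2 and 2 over the list alone), with a median of 0.09, a mean of −0.04 and a camera direction of up (adjusted p = 0.95). Of 25 Wnt genes the receptor genes Fzd9, Fzd10 and Lgr6 rose and none fell (4 and 0 over the list alone; median 0.21, adjusted p = 0.0618). All 3 calls were lost without eGFP replicate 1 (0.098, 0.123 and 0.0594), eGFP replicate 5 (0.188, 0.116 and 0.104), eGFP/tdTomato replicate 3 (0.133, 0.139 and 0.0798) or eGFP/tdTomato replicate 5 (0.107, 0.173 and 0.0529).

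Metabolic lists were slightly higher with both reporters, with 0 members called over all genes or over the list alone: cholesterol synthesis (23 genes, median 0.39, adjusted p = 2.03e-06, or 0.302 with an estimated correlation), glycolysis (16 genes, 0.28, adjusted p = 0.00787, or 0.424) and fatty acid oxidation (18 genes, 0.41, adjusted p = 1.88e-05, or 0.306). The glycolysis call was lost without eGFP replicate 1 (0.768). Camera sets a list against all genes, whose median was −0.02 here, while the 10146 genes with a mean of at least 10 CPM had a median of 0.14. Of 15 complement and phagocytosis genes C1qa, C1qb and C1qc fell (1 higher and 4 lower over the list alone; median −0.01, adjusted p = 0.657). These genes also belong to the microglia and macrophage list, of which 11 of 19 members fell. None of the 7 erythrocyte genes passed (0 over the list alone; median −0.21, adjusted p = 0.205), and none of the 7 Schwann cell genes (1 lower over the list alone; median −0.67, adjusted p = 0.00752, or 0.103 with an estimated correlation).

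Against the tdTomato fraction, signalling genes were mostly higher with both reporters. Notch had 12 of 19 members higher and 3 lower (13 and 3 over the list alone; median 2.52, adjusted p = 0.00458, or 0.251 with an estimated correlation), with Hey2 at 6.17 ± 0.26. Hedgehog had 10 of 13 higher and 3 lower (10 and 3; median 2.95, adjusted p = 0.0109, or 0.182 with an estimated correlation), BMP and TGF-beta 16 of 24 and 4 (18 and 4; median 2.95, adjusted p = 6.45e-05, or 0.0484) with Id3 at 7.05 ± 0.35, and Wnt 14 of 25 and 1 (15 and 1; median 2.44, adjusted p = 2.43e-05, or 0.0652). Cholesterol synthesis was lower, with 1 of 23 members higher and 15 lower (1 and 15; median −0.81, adjusted p = 4.61e-10, or 0.162 with an estimated correlation) and Ebp, a sterol isomerase gene, at −2.39 ± 0.18. Fatty acid oxidation was higher in 13 of 18 members (13 and 1; median 1.13, adjusted p = 6.7e-05, or 0.337), with Cpt1a 17.4-fold higher, and glycolysis split into 5 higher and 2 lower (6 and 3; median 0.49, adjusted p = 0.103), with Aldoc 82.3-fold higher. Complement and phagocytosis had 11 of 15 higher and 1 lower (11 and 1; median 4.73, adjusted p = 1.54e-05, or 0.144). The remaining lists were not called: motor neuron (1 higher, 1 lower; median 1.58, adjusted p = 0.996), endothelium (4 and 1, or 7 and 1 over the list alone; 1.28, 0.369), erythrocyte (0 and 0; 0.36, 0.592), Schwann cell (4 and 1; 1.53, 0.294) and matrix proteoglycans (5 and 4; 0.23, 0.996).

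Between the eGFP and tdTomato fractions, transmitter and ion transport genes were higher in the eGFP fraction in 17 of 18 cases (17; median 4.14, adjusted p = 5.72e-14, or 0.0531 with an estimated correlation), white matter genes in 10 of 12 (10 and 1 lower; 5.83, adjusted p = 6.5e-10, or 0.0687), grey matter genes in 10 of 12 (10; 3.50, adjusted p = 3.52e-08, or 0.0687) and synapse-regulating factors in 15 of 21 with 2 lower (16 and 2; 2.60, adjusted p = 3.29e-07, or 0.0707). Dorsal factors were higher in 12 of 18 with 1 lower (13 and 1; 4.48, adjusted p = 3.73e-05, or 0.0531), with Zic4 164-fold higher, and ventral factors in 7 of 14 with 5 lower (8 and 5; 1.92, adjusted p = 0.355). Notch had 13 higher and 3 lower (13 and 4; 1.54, adjusted p = 0.0146, or 0.31), Hedgehog 9 and 2 (10 and 2; 2.94, adjusted p = 0.00469, or 0.118), BMP and TGF-beta 16 and 3 (17 and 3; 3.09, adjusted p = 3.48e-05, or 0.0531) and Wnt 15 and 1 (16 and 1; 2.32, adjusted p = 5.69e-05, or 0.0707). Cholesterol synthesis had 1 higher and 20 lower (1 and 21; −1.24, adjusted p = 4.37e-13, or 0.0943), fatty acid oxidation 9 and 1 (9 and 2; 0.63, adjusted p = 0.0113, or 0.518), glycolysis 5 and 3 (0.30, adjusted p = 0.389) and complement and phagocytosis 14 and 0 (4.25, adjusted p = 9.78e-08, or 0.0707). Motor neuron (3 and 1; 2.17, 0.555), erythrocyte (1 and 0; 0.51, 0.307), Schwann cell (5 and 1; 2.53, 0.0595) and matrix proteoglycan genes (5 and 3; −0.14, 0.646) were not called.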
